A study of Mus musculus with 8 samples.

How the data were processed

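RNA of mouse GV oocytes was measured in 8 libraries, 4 of control oocytes and 4 of Kiaa1429 cKO oocytes, about 20 oocytes each. Per the labels' protocols, females received 5 IU of PMSG and oocytes of at least 70 µm were taken 48 hours later. RNA was reverse transcribed with oligo-dT primers and template switching, amplified, tagmented and sequenced as pairs. Such libraries do not mark strand. The labels call the mice 20 days old in one field and 3 weeks old in another.

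The authors deposited whole-number counts per exon ID, 1 file per library. STAR, HTSeq and the build mm10 are named in the submitters' processing notes. Their versions, options and annotation release are not given in the sources used here. Each file lists 496288 exon IDs and 5 summary rows that name no exon, which stayed out of library sizes and tests. Reads, or all reads, means here the sum of counts on exon IDs, ambiguous reads and reads outside every exon ID. The other summary rows are left out of it. The deposited counts on exon IDs are 14.6% to 15.6% of reads. Reads that meet more than 1 exon ID are set apart as ambiguous, 72.9% to 80.4% of reads, and reads outside every exon ID are 5.01% to 12.0%. An exon is therefore measured mainly where no other exon ID of the files overlaps it and where a read pair does not cross into another exon ID; exons with no such bases by the annotation used here hold 0.212% of counts, and those with at least 150 such bases 97.2%. Of all counts 76.7% lie on last exons, 9.46% on internal and 4.95% on first exons. Oligo-dT priming and the counting rule may each add to the share on last exons and were not separated. Genes whose exons all overlap, or are short, have few or no countable reads, and a low count is not evidence of low expression.

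Exon IDs were matched to GENCODE M21 on the same build (GRCm38). Ignoring versions, 494230 (99.6%) matched and 2058, holding 0.252% of counts, did not and were left out. Gene counts are sums over a gene's exon IDs. Genes were kept by filterByExpr at its default (minimum count 10), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with group as the only term, two-sided, Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size over the root of the F statistic. Scaling by RLE or upper-quartile factors moved all log2 fold changes by -0.00338 and 0.00807 relative to TMM, and no scaling would move them by 0.159. Exon usage was tested with diffSpliceDGE of edgeR on exons kept by the same filter in genes with at least 2 such exons. Its coefficients were converted from natural logs to log2. Usage percentages are over the tested exons of a gene. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1). Single values per library were compared by an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. Ratios of few counts have 95% Clopper-Pearson intervals, which cover counting error only, as amplified reads are not independent molecules. At this depth 3 counts in a library are 0.594 to 0.708 CPM.

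The tests of the comparisons in the results, the gene lists, the marker genes, the rule for named genes and all but 3 alternatives were fixed before the data were examined. The comparisons of gene classes, of reads outside exon IDs and of summed markers were added after, and the tests of explanations were written later. The rule takes Virma and every tested m6A writer, the 12 largest changes in each direction among called genes with a mean of at least 10 CPM, groups that do not overlap and an official symbol, up to 4 members of smallest p per list, the 12 genes of smallest p for exon usage, and a list member that changed alone. Zp3 and the cell type markers named beside it come from the fixed marker lists. The 27 lists name 1022 genes, of which 577 could be tested. Some genes that the rule takes are not reported here.

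The tests were tried on simulated counts with the real means, library sizes and dispersions for control against Kiaa1429 cKO. With 200 changed genes among 9784 tested, 10.4% of 1.5-fold, 52.2% of 2-fold and 90.9% of 4-fold changes were called, and 6 unchanged genes were called. In the data 5856 of 10673 genes were called, which makes the adjusted cutoff less strict than in the simulation. These shares are therefore not the power in the data. With 200 changed genes among 847 tested for exon usage, 17.9%, 49.3% and 92.4% were called at these sizes, with 7 unchanged genes called, and estimated usage changes followed the true ones with a slope of 1.03. Only genes with more than 2 kept exons were simulated, while the real test took genes with at least 2. These shares and this slope thus do not carry over to genes with 2 tested exons. The median estimated sizes were 0.334, 0.673 and 1.415 on the log2 scale where the true ones were 0.498, 0.820 and 1.362, so small changes were estimated too small.

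No pair of libraries of the same group agreed within sampling noise (chi-square per gene 5.11 to 25.4), so all 8 were counted as separate. Pairs across the groups were not compared in this way. Alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, limma diffSplice, thresholds, a replicate block and leaving out each library. Leaving out last exons, exon IDs of another version, and control 4 with cKO 4 were chosen after seeing the data.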

Results

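The series profiled polyadenylated RNA of mouse germinal vesicle (GV) oocytes, the fully grown oocytes arrested in meiotic prophase. By design the control oocytes lose 1 copy of the gene Kiaa1429 and the others lose both. Kiaa1429, now named Virma, encodes a large subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Zp3-Cre, a recombinase driven by an oocyte promoter, removed the floxed allele during oocyte growth. Controls carried 1 floxed allele with Zp3-Cre and the conditional knockouts (cKO) carried floxed alleles on both chromosomes with Zp3-Cre. Each group had 4 libraries of about 20 oocytes each, collected 48 hours after 5 IU of PMSG, a hormone that drives follicle growth, from C57BL/6 females given as 20 days old. Counts on exons ranged from 4247471 to 4790038 per control library and from 4399190 to 5064008 per cKO library. The labels speak of 4 separate experiments, but do not say which libraries belong to which animals, so the p-values measure the spread between these libraries.

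The comparison asks how the oocyte transcriptome differs when both copies of Virma are lost rather than 1. Virma itself (ENSMUSG00000040720.15, chromosome 4, 11485958 to 11550684, mm10, plus strand) stood at 67.9 ± 11.2 CPM (counts scaled to library size, mean ± SD, n = 4) in controls and at 19.4 ± 3.26 CPM (n = 4) in the cKO. Its log2 fold change was -1.81 (SE 0.18, adjusted p = 1.02e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), which leaves 28.6% of the control level. The control libraries ranged from 57.1 to 82.0 CPM and the cKO libraries from 17.0 to 24.2 CPM, so every library went with its label. Of the 27 exon IDs of Virma, 16 held any count and 2 held enough to be tested. Both fell. The last exon (11549545 to 11550684, coding and 3' UTR), which held 74.9% of the gene's counts, fell by 1.83 on the log2 scale (SE 0.21, adjusted p = 3.90e-07 over the tested exons of the gene). An internal coding exon of 1141 bases (11513028 to 11514168) had a log2 fold change of -0.99 (SE 0.38, adjusted p = 0.0186). An alternative last exon (11526595 to 11527621) held 22 counts in the controls and 0 in the cKO. Which exons the floxed allele removes is not given in the sources used here, so these exons may lie outside the deleted part and the level checks the labels only through the amount of RNA.

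Other genes of the m6A machinery moved as well. Of 11 listed writer genes 6 had enough counts to be tested. Mettl3, Mettl14, Wtap, Cbll1 and Mettl5 did not, so their levels are not known here. Besides Virma, 3 of the other 5 tested writer genes fell and 1 rose. Rbm15, an adaptor that recruits the writer complex to RNA, fell from 346 ± 97.3 to 153 ± 12.9 CPM (log2 fold change -1.18, SE 0.19), and its paralog Rbm15b fell from 42.8 ± 11.4 to 21.6 ± 2.40 CPM. Mettl16, a separate m6A methyltransferase, rose from 17.4 ± 1.59 to 37.7 ± 5.97 CPM. Zcchc4, which methylates ribosomal RNA, had a log2 fold change of -0.56 (SE 0.22, adjusted p = 0.0413, edgeR), a call that was lost under 10 alternative settings. Zc3h13, a scaffold of the complex, had a log2 fold change of -0.25 (SE 0.14, adjusted p = 0.149, edgeR) and was called lower when only protein-coding genes were scaled and tested. Of 8 tested readers and erasers 3 rose and 2 fell. The demethylase Alkbh5 fell from 3005 ± 450.5 to 1852 ± 122.5 CPM, and the reader Ythdf1 rose from 70.5 ± 17.2 to 134.6 ± 20.6 CPM. Hnrnpc was called higher with all its exons (log2 fold change 0.59, SE 0.12) and called lower with last exons left out (-0.71).

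**Figure D1:**
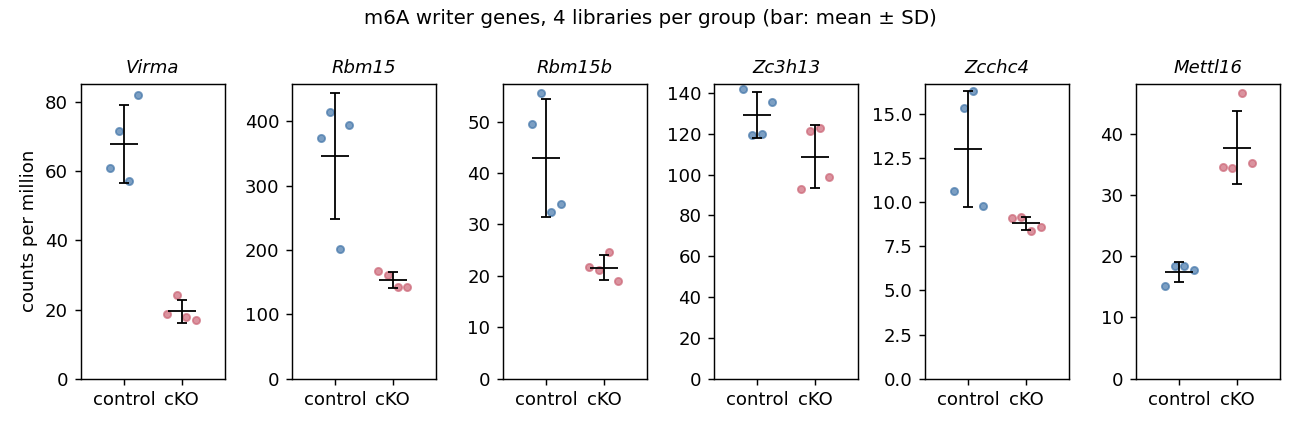
CPM (vertical axis, each panel on its own scale from 0) of the 6 tested m6A writer genes in 4 control and 4 cKO libraries, with the mean and SD as black bars. Virma, Rbm15 and Rbm15b are lower in each of the 4 cKO libraries than in each control library, and Mettl16 is higher.

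The difference between the groups reached over the transcriptome. Of 10673 genes tested, 2883 (27.0%) were higher and 2973 (27.9%) lower in the cKO (edgeR, adjusted p under 0.05), with median log2 fold changes of 1.10 and -1.18. The groups did not overlap in 5347 genes (50.1%), where chance gives 2.86%. The first principal component held 76.4% of the variance and separated the groups. Correlations of log2 CPM were 0.963 to 0.984 within a group and 0.830 to 0.875 between groups. With an absolute log2 fold change of at least 1 as well, 1616 genes were higher and 1801 lower. Because 76.7% of counts lie on last exons, the gene levels are mostly levels of last exons. With these left out, 4178 genes could be tested, of which 970 were higher and 993 lower, and 94.1% of the 2289 called genes that could be tested had the same sign.

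**Figure D2:**
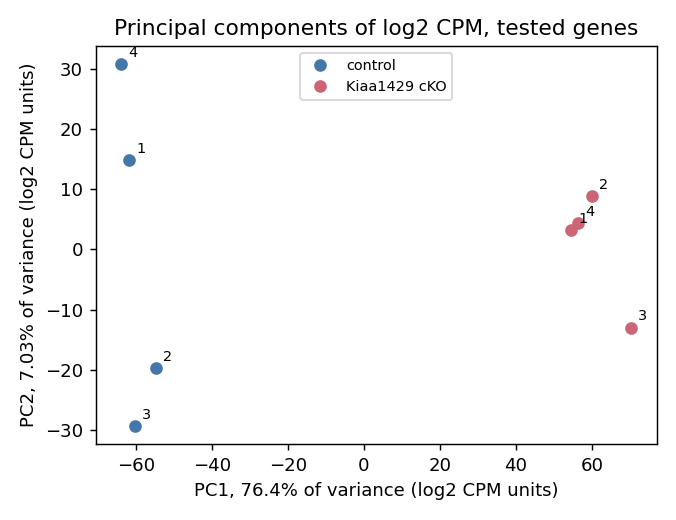
Principal components of log2 CPM over the tested genes, each point a library with its replicate number. The 4 control libraries lie between -63.9 and -54.8 on the first component and the 4 cKO libraries between 54.5 and 70.3.

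Among the largest rises, Prrg3, a membrane protein with a Gla domain, had 4 counts in all controls together and 688 in the cKO, a ratio of 164.5 (95% Clopper-Pearson interval 64.0 to 605.6, counting error only). Grxcr2, a glutaredoxin-related protein of the inner ear, went from 1.21 ± 0.939 to 112.7 ± 14.7 CPM. Transcription factors among these genes were Skor1 (5 to 468 counts), Msx1 (6 to 411 counts) and Hoxd1 (9 to 464 counts), both homeobox genes, and Zfp800 (8 to 402 counts). Dusp6, a phosphatase of ERK, went from 1.31 ± 1.51 to 55.3 ± 16.7 CPM. Retreg1, a receptor for autophagy of the endoplasmic reticulum, went from 1.40 ± 0.420 to 45.3 ± 8.40 CPM. Gstt3, Prl2a1 and Trap1a were also among them, with log2 fold changes of 5.49, 5.43 and 4.65. Prl2a1 belongs to a family of near-identical prolactin genes, and its counts are uncertain for that reason.

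Among the largest falls, Bach2, a transcriptional repressor, fell from 333.7 ± 32.5 to 35.3 ± 5.57 CPM (log2 fold change -3.24, SE 0.15, adjusted p = 2.47e-09, edgeR). Zfp616, a zinc finger gene, fell from 276.4 ± 35.2 to 25.0 ± 4.20 CPM, and Lrrtm2, a leucine-rich repeat membrane protein, from 229.5 ± 88.6 to 19.5 ± 6.36 CPM. Slamf1, an immune cell receptor, fell by 4.34 on the log2 scale, and the ubiquitin ligase Nedd4l, Olfml1 and Myl4, a myosin light chain, had log2 fold changes of -4.28, -4.16 and -3.77. Defb41, Wdr5b, Tnfrsf21 and the non-coding RNA Redrum had log2 fold changes of -4.05, -3.34, -3.19 and -3.29. Igf1os, antisense to Igf1, fell from 65.3 ± 7.42 to 2.97 ± 0.704 CPM. The libraries do not mark strand, so its reads cannot be told from those of overlapping genes.

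Splicing and 3' end processing factors held more risen than fallen members, as did the 7991 tested protein-coding genes together (30.4% higher, 23.5% lower). Of 28 SR and hnRNP regulators 13 rose and 2 fell. Srsf7 rose from 63.9 ± 14.9 to 261.7 ± 31.0 CPM (log2 fold change 2.03, SE 0.17), Srsf10 from 449.6 ± 61.6 to 935.5 ± 100.9 CPM and Tra2b from 108.6 ± 12.1 to 217.5 ± 2.78 CPM. Of 14 cleavage and polyadenylation factors 6 rose and none fell. Clp1, an RNA kinase of the complex, rose from 12.5 ± 3.08 to 89.6 ± 8.21 CPM. Of 37 core spliceosome genes 9 rose and 2 fell, with Prpf4 up by 2.42 and Cdc5l by 3.70 on the log2 scale and Prpf38a at -0.70. Among 26 genes of RNA polymerase II and elongation 6 rose and 7 fell, with Gtf2b at a log2 fold change of 0.95 and Med1 at -1.64.

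Oocyte genes split. Of 12 zona pellucida and secreted factors 5 fell and 1 rose. Bmp15 and Gdf9, growth factors through which the oocyte acts on its cumulus cells, fell from 18800 ± 3751 to 7334 ± 1455 CPM (log2 fold change -1.36, SE 0.16) and from 13580 ± 2389 to 8130 ± 562.2 CPM. The 1 that rose was Kitl, by 0.69, which also stands on the cumulus and granulosa marker list, so its rise may not speak for the oocyte. Zp3, which encodes a zona protein and whose promoter drives the recombinase, stood at 235.4 CPM in controls and 226.9 in the cKO (adjusted p = 0.770, edgeR). Of 12 oocyte transcription factors 5 fell and 1 rose. Obox7 fell from 996.8 ± 164.3 to 275.4 ± 64.9 CPM and Bnc1 from 484.5 ± 74.7 to 226.7 ± 13.8 CPM, while Sohlh2 rose from 11.8 ± 4.97 to 173.0 ± 6.35 CPM. Obox genes have near-identical copies, and reads between them may be split. Of 19 maternal effect factors 4 rose and 5 fell, with Nlrp2 at -1.05 and Ube2a at 0.96. Of 20 genes of mRNA storage, translational control and decay 4 rose and 1 fell, Zfp36l2, which destabilises AU-rich mRNAs, by 2.16 and Ddx6 by 1.05, both upward. Of 18 growth signalling genes 3 rose and 5 fell. Gjc1, a connexin, rose by 3.32 and Pdpk1, a kinase upstream of AKT, had a log2 fold change of -0.86.

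Among 32 meiotic resumption and cell cycle genes 7 rose and 7 fell. The 2 Wee kinases, inhibitors of CDK1, moved apart. Wee1 rose from 97.1 ± 23.6 to 241.1 ± 45.1 CPM, and Wee2, the oocyte form, fell from 1388 ± 301.1 to 711.9 ± 75.6 CPM. Mos, the kinase that activates MAPK in oocytes, fell from 4853 ± 423.4 to 3184 ± 233.9 CPM. Of 44 spindle, kinetochore and cohesin genes 17 rose and 5 fell, Kif11 from 71.9 ± 4.69 to 157.8 ± 16.3 CPM and the spindle checkpoint kinase Ttk by 3.87 on the log2 scale.

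Chromatin genes changed in both directions. Of 33 histone modification and remodelling genes 10 rose and 5 fell. Kmt2a, a histone H3 lysine methyltransferase, rose from 1.64 ± 0.151 to 29.5 ± 2.36 CPM and Chd1 from 17.8 ± 4.51 to 66.6 ± 7.99 CPM. Of 12 DNA methylation genes 4 rose and 1 fell, Dnmt3c by 3.03 and Tet2 by 1.13 upward. Of 27 replication-dependent histone genes 6 rose and 12 fell, Hist1h4d by 1.94 upward and Hist1h2aa with a log2 fold change of -2.26. Their near-identical copies make single members uncertain. Of 23 piRNA and transposon silencing genes 7 rose and 5 fell. Ago2 fell from 205.8 ± 40.3 to 57.6 ± 8.97 CPM, while Ago1, Ago3 and Ago4 rose by 3.96, 0.69 and 1.04. Of 10 zygotic genome activation markers 4 rose and 3 fell. Tcstv3 had a log2 fold change of -1.51 and Usp17lc went from 9 to 248 counts; both belong to multicopy families.

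Of 17 p53 targets and apoptosis genes 11 rose and 2 fell. Sesn1 rose from 6.97 ± 2.13 to 50.8 ± 12.3 CPM and Perp from 11.4 ± 2.65 to 36.4 ± 6.53 CPM, while Casp8, an initiator caspase, fell from 107.3 ± 25.3 to 27.9 ± 4.81 CPM. Of 30 DNA damage and repair genes 2 rose and 8 fell, Xrcc5 with a log2 fold change of -0.99 and Rnf168 of -1.15. Of 19 unfolded protein and integrated stress response genes 5 rose and 6 fell. Dnajb9, a chaperone of the endoplasmic reticulum, rose from 77.2 ± 15.1 to 615.0 ± 80.2 CPM and Chac1 from 20.6 ± 6.88 to 89.3 ± 4.48 CPM, while Atf3 fell from 12.3 ± 2.98 to 2.98 ± 0.980 CPM. Of 32 cytosolic ribosomal protein genes 16 rose and 2 fell, Rpl10l from 58.4 ± 18.5 to 249.6 ± 38.1 CPM. These genes have many processed copies, and 32 is the number with countable reads out of 86. Of 39 nuclear-encoded oxidative phosphorylation genes 7 rose and 7 fell, with Atp5g3 at 2.06 and Atp5c1 at -1.15. Of 22 proteasome genes 5 rose and 1 fell, Psmd9 by 0.86 upward and Psmb11 with a log2 fold change of -1.99. Of 13 mitochondrial genome genes only mt-Nd2 changed, from 1079 ± 154.7 to 760.3 ± 91.5 CPM, though mt-Co2 and mt-Nd1 were called higher under 3 and 1 alternative settings. The mitochondrial share of counts was 2.08% ± 0.458 in controls and 2.36% ± 0.321 in the cKO (n = 4 each, exact permutation p = 0.314, two-sided).

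None of the 27 lists passed as a set with camera, which compares a list with all other genes (0 at adjusted p under 0.05 and 5 at an unadjusted p under 0.05; 0 and 0 with an estimated correlation). The smallest adjusted p was 0.175, and 0.677 with an estimated correlation. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, called 15 lists, 10 upward and 5 downward. The counts adjusted over the list alone were equal to those over all genes in 22 lists and differed by at most 2 genes per direction in the other 5. Signs differed within 2 lists: the stress response list had a median log2 fold change of -0.16, a mean of 0.25 and an upward camera direction, and growth signalling a median of -0.06, a mean of 0.03 and a downward one.

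**Figure D3:**
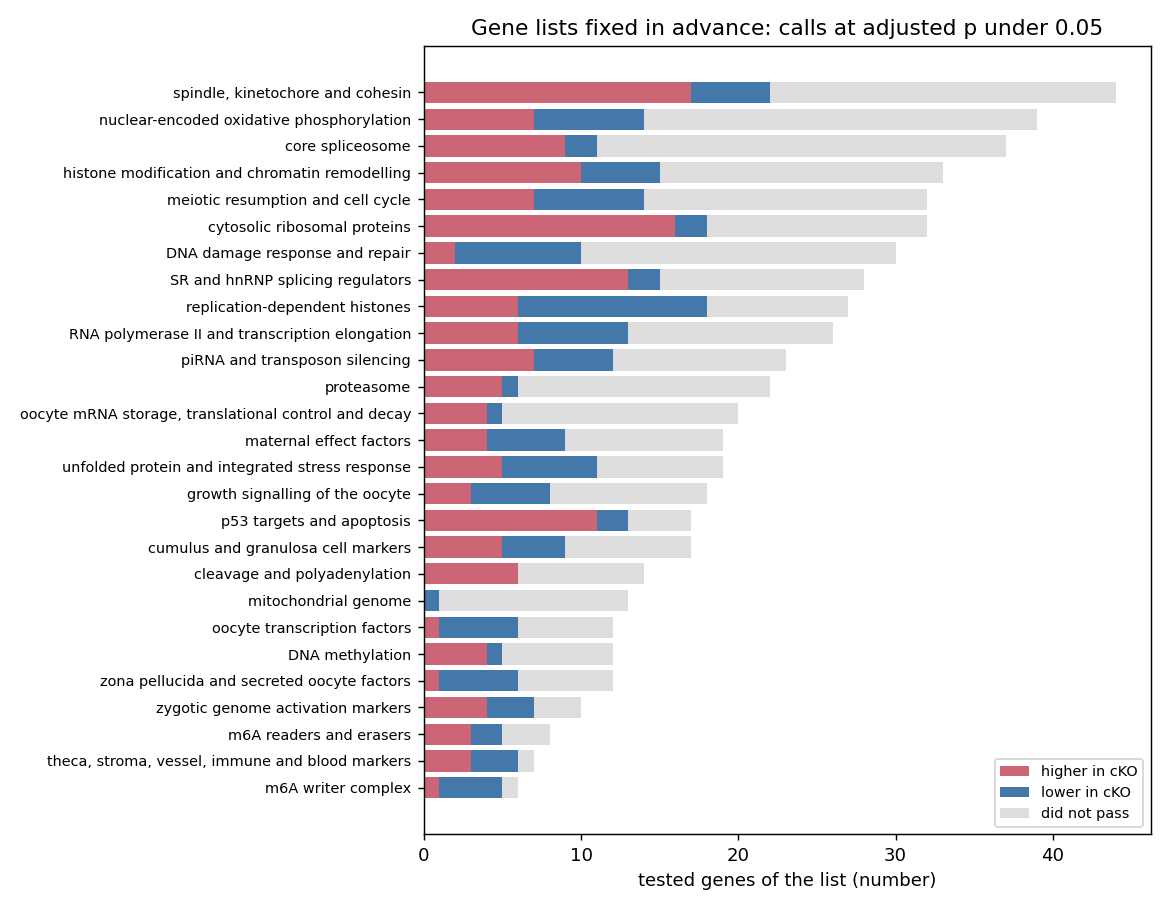
Number of tested genes (horizontal axis) of each list that were higher, lower or did not pass at an edgeR adjusted p under 0.05 in the cKO against control. The SR and hnRNP list holds 13 higher and 2 lower genes, the p53 list 11 and 2, and the replication-dependent histones 6 and 12.

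Markers of the cells around the oocyte were read beside these groups. Of 17 cumulus and granulosa genes 5 rose and 4 fell, and the 16 marker genes summed to 380.4 ± 144.9 CPM in controls and 702 ± 195 in the cKO (n = 4 each, exact permutation p = 0.0571). Nr5a2, a nuclear receptor of granulosa cells, rose from a mean of 138.7 to 322.8 CPM, a large part of the rise in the sum. Over the cKO libraries it lay between 296.8 and 358.1 CPM and did not follow Inha. Inha rose from a mean of 66.1 to 173.5 CPM, with 45.4 in cKO replicate 1 and 310.8 in cKO replicate 4, and Ptgs2 rose by 2.88, while Cyp19a1 fell by 1.11 and Fshr had a log2 fold change of -1.64. Of 7 genes on the theca, stroma, vessel, immune and blood list 3 rose and 3 fell. C1qa, a complement gene, had 3 counts in all controls and 135 in the cKO, a ratio of 43.1 (interval 14.4 to 211.4), and the macrophage and leukocyte genes Ptprc, Adgre1 and Cd74 had 0 CPM in all 8 libraries. Cd68, another macrophage gene, stood at 0.240 and 0.672 CPM, too low to be tested. Counts of 0 or near it may reflect few countable bases, so they do not show that such cells were absent. The oocyte gene Zp2 itself held only 4.82 CPM in controls and 5.45 in the cKO. The 8 immune and blood markers summed to 0.767 ± 0.564 and 7.94 ± 1.72 CPM (n = 4 each, exact permutation p = 0.0286), most of it C1qa in the cKO. The 8 theca and stroma markers summed to 2.30 and 2.41 CPM and the 4 vessel markers to 7.97 and 8.31 CPM in controls and cKO. The 10 oocyte markers summed to 35720 ± 5919 CPM in controls and 18170 ± 1719 CPM in the cKO (n = 4 each, exact permutation p = 0.0286), most of it Bmp15 and Gdf9, and 4 of the 10 fell. The oocyte marker Bmp15 alone exceeded the summed markers of each of the other cell types by far in every library, and Kitl stands on the oocyte list as well. Genes differ in countable bases, so CPM compared between genes do not measure the share of cells.

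The share of counts on gene classes shifted. Of 1293 long non-coding RNA genes 684 were lower and 209 higher (median log2 fold change -0.71), against 1879 lower and 2426 higher of 7991 protein-coding genes (median 0.10). When only protein-coding genes were scaled and tested, 2167 were higher and 2088 lower. Long non-coding RNAs took 5.68% ± 0.503 of counts in controls and 3.90% ± 0.186 in the cKO, and TEC genes, provisional models from transcript evidence, took 0.715% ± 0.1251 and 0.247% ± 0.0130. Reads outside all exon IDs were 11% ± 0.883 of reads in controls and 5.77% ± 0.531 in the cKO (n = 4 each). Ambiguous reads, which enter no gene or exon count, went the other way, with 73.8% ± 1.07 and 79.3% ± 0.751 of reads (n = 4 each). For each of these the groups did not overlap (exact permutation p = 0.0286, the smallest that 4 against 4 can give; 0.0452 after Benjamini-Hochberg over 19 library measures). Counts on exon IDs were 15.2% ± 0.324 of reads in controls and 14.9% ± 0.269 in the cKO (n = 4 each, exact permutation p = 0.4). The reads left out of the level and usage tests thus differed between the groups in where they fell, which limits those tests. Genes with at least 1 count numbered 19829 ± 555.7 in controls and 21046 ± 625.3 in the cKO (n = 4 each, exact permutation p = 0.0286).

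**Figure D4:**
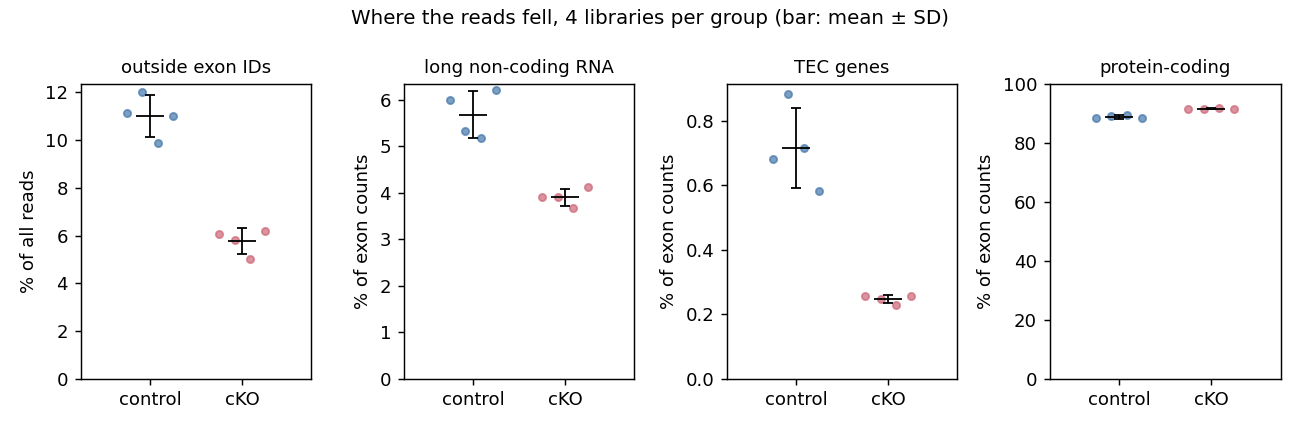
Share of reads outside exon IDs (percent of all reads) and shares of exon counts on long non-coding RNA, TEC and protein-coding genes (percent of exon counts), 4 libraries per group, with mean and SD as black bars and axes from 0. The cKO libraries hold 5.01% to 6.19% of reads outside exon IDs and the controls 9.86% to 12.0%.

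Exon usage, the share of a gene's counts on each exon, changed in 671 of 2847 genes (23.6%, edgeR diffSpliceDGE, Simes test, adjusted p under 0.05). Of 6931 exons 443 had higher and 488 lower usage in the cKO. Of the 671 genes 62.4% had also changed in level, against 58.0% of the genes tested for usage. Several genes moved between alternative last exons. In Hhat, an acyltransferase of Hedgehog proteins, a non-coding last exon on chromosome 1 (192654960 to 192657604) held 42.3% ± 5.10 of counts in controls and 3.46% ± 0.821 in the cKO (log2 usage change -3.60, adjusted p = 3.03e-15, edgeR diffSpliceDGE). In Crb1, a polarity protein, a last exon (chromosome 1, 139245617 to 139249075) went from 50.3% ± 2.88 to 6.06% ± 3.32, and in Lrriq3 one (chromosome 3, 155100965 to 155102626) from 32.0% ± 4.13 to 3.42% ± 1.963. Other last exons gained. In Ptprd, a receptor phosphatase, one (chromosome 4, 77917524 to 77918356) went from 0.790% ± 0.0888 to 32.5% ± 4.22, and in Auh (chromosome 13, 52886428 to 52887297) from 4.50% ± 1.16 to 25.6% ± 2.11. The last exon of Fancc (chromosome 13, 63321299 to 63321662) went from 0.570% ± 0.123 to 17.2% ± 4.60. That of Pcnx4 (chromosome 12, 72579304 to 72580119) went from 3.11% ± 0.554 to 21.6% ± 2.57. Fancc and Pcnx4 had no other tested last exon, so these gains are measured against first or internal exons and show no move between last exons. Internal coding exons changed in both directions. One of Dppa2 fell from 22.4% ± 2.70 to 4.02% ± 0.826 and one of Dscam from 5.28% ± 0.607 to 0.385% ± 0.194, while those of Cage1, Dnah8 and Myo9a rose to 37.4% ± 5.54, 11.7% ± 1.25 and 10.8% ± 1.81 from 2.71% ± 0.535, 0.281% ± 0.247 and 0.135% ± 0.270.

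**Figure D5:**
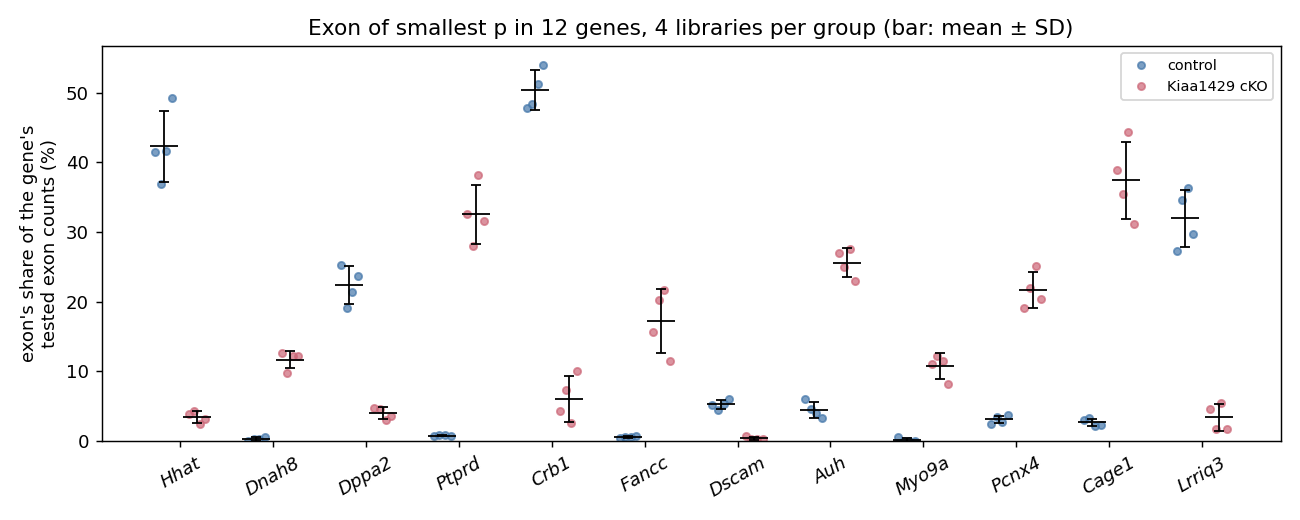
Share of the gene's tested exon counts (percent, vertical axis) on the exon of smallest p in 12 genes, in 4 control and 4 cKO libraries, with mean and SD as black bars. The groups do not overlap in any of the 12 exons.

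Usage was called in 12.6% of first, 14.4% of internal and 12.6% of last exons, and in 39.6% of 48 exons of single-exon transcripts, 5 higher and 14 lower. The mean log2 ratio of last to internal exon counts over 1713 genes was 2.09 ± 0.107 in controls and 2.14 ± 0.0684 in the cKO (n = 4 each, difference 0.0431, exact permutation p = 0.571), and that of first to internal exons over 570 genes differed by -0.0225 (p = 0.771, exact permutation). Reads that cross from one exon ID into another were not counted on either, so short exons are measured mainly where reads stay within them.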

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

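Values are listed here when they passed a limit on how far the highest or lowest of 4 libraries lies from the others, as a share of the group's range. Of 334 groups of 4 looked at, 21 (6.29%) passed it, where chance gives about 1 in 20, so most single cases carry little weight. No test in this part was chosen after the result was seen, and no explanation was tested for these values.

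Among genes in the cKO, replicate 3 stood apart for Mettl16 (46.6 CPM against 34.4 to 35.2 in the others, ratio of the gap to the range 0.936), Prpf38a (64.1 against 70.7 to 71.5, 0.886), Wrn (66.2 against 72.5 to 73.6, 0.850) and Hist1h1e (15.3 against 13.8 to 14.0, 0.899). Replicate 2 stood apart for Cpsf2 (141.5 against 114.1 to 118.7, 0.834) and Kitl (63.3 against 52.3 to 54.1, 0.835). Replicate 1 did for Obox7 (372.4 against 237.8 to 250.9, 0.902) and Srsf10 (1086 against 874.9 to 898.8, 0.887), and replicate 4 for Bnc1 (206.2 against 231.8 to 236.5, 0.847).

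Among controls, replicate 3 stood apart for Clp1 (7.89 CPM against 13.8 to 14.3, 0.920), Mos (5484 against 4580 to 4697, 0.871) and Tcstv3 (30.0 against 45.2 to 48.0, 0.846), and replicate 2 for Ago3 (101.2 against 141.5 to 143.8, 0.945). Skor1 in control replicate 1 (0.444 CPM, 0.884) and Hist1h3c in control replicate 2 (0.479 CPM, 0.840) rest on a few counts.

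For exon usage, Dnah8 in cKO replicate 2 was 9.84% against 12.2% to 12.6% (0.854), and Myo9a in control replicate 1 was 0.541% where the other controls had 0 (1). For the libraries as a whole, exon counts were highest in control replicate 1 (0.933) and in cKO replicate 4 (0.902), all reads in cKO replicate 4 (0.830), and the share of ambiguous reads in cKO replicate 3 (80.4% against 78.8% to 79.0%, 0.885).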

How the results depend on the processing

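Leaving out last exons, exon IDs of another version, and control 4 with cKO 4 were chosen after the results were seen. Virma stayed lower under every setting run (log2 fold change -1.34 to -1.92). Genes higher and lower numbered 2602 to 3068 and 2764 to 3018 without 1 library, and no gene called in the main test was called in the opposite direction except 32 with last exons left out. That setting tests 4178 genes on fewer counts each and gave 970 higher and 993 lower; of 2289 earlier calls it could test, 754 higher and 907 lower were called again. It turned Hnrnpc to -0.71 (the cause was not tested). A fold limit gave 1616 and 1801. Genes with changed exon usage were 614 to 745 without 1 library, 359 with a mean exon CPM of at least 5 (fewer exons tested) and 1135 with at least 1 count in 3 libraries (more exons tested). Under these 2 filters exons with higher usage were 232 and 812 and with lower usage 261 and 881; limma diffSplice gave 804 and 813, and the cause was not tested. Without a filter 5 Virma exons changed, from 16 tested. Without 1 library 2 to 3 did, the higher number without cKO replicate 2 or 3. Lists past the threshold were 0 with camera under each setting and 15 with fry, which tests another question.

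The ratio of last to internal exons moved between -0.00521 and 0.0769 without 1 library, turning sign without control replicate 3. That of first to internal exons moved between -0.0606 and 0.0347, turning without control replicates 2 or 3 or cKO replicate 2 (0.0148, 0.0347 and 0.0071), and was 0.0818 with at least 50 counts in every library. None passed the exact test. With at least 5 counts the gain in genes detected was 645.2 (exact permutation p = 0.0571), and 484.5 with libraries thinned to equal depth (exact permutation p = 0.0286).

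The replicate numbers did not clearly pair the libraries. Correlations of deviations within the same number were 0.104, -0.0516, 0.1 and 0.062. Their means with other numbers were -0.0249, 0.00486, -0.0427 and -0.00431, and 2 of 4 controls correlated best with their own number. Correlations this weak do not exclude pairing. With the replicate block 2885 genes were higher, 2908 lower, 652 had changed exon usage (430 exons higher, 480 lower), 0 lists passed and Virma was at -1.80 with 2 exons changed. Without control 4 and cKO 4, which hold the most cumulus marker counts of their groups, 2526 genes were higher, 2686 lower and 551 changed in usage. Of 133 other named genes, Igf2bp3 and Zcchc4 lost their call under 9 and 10 settings. Cpsf2, Lig4, Psmd7, Rictor, Rpl7l1, Serpine2 and Wrn lost it only with last exons left out. At this depth and number of libraries 52.2% of simulated 2-fold changes in level were called.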

Other observations

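Tests chosen after the result was seen are the count of receptor genes without reads, their rate without the 10 highest, the spread of the cumulus and of the oocyte markers, the comparison of Zp3 with Bmp15 and the use of the planned ratio of last to internal exons against a shift of last exons; the other tests were written before their results, on patterns picked from the same data.

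Reads outside coding genes fell together in the cKO: of 940 non-coding genes (long non-coding RNA and TEC) outside every coding gene 490 were lower and 153 higher. Their median log2 fold change was -0.683 (95% bootstrap interval -0.769 to -0.599). The bootstrap drew genes, which are not independent, so the interval leaves out the spread between libraries. This median argues against intron reads of coding genes as the whole cause. Without the 20 most abundant non-coding genes 64.3% of the fall in share remained, so a few genes do not account for it. Genomic DNA in the controls was tested on olfactory, vomeronasal and trace amine receptor genes, taken as silent. As it needs, they held control counts per base at 131% ± 11.4 of the rate of reads outside exons (70.9% ± 5.52 without the 10 highest genes). In the cKO they held 186% ± 7.74 (107.6% ± 3.27 without the 10 highest genes). Their counts per megabase were 1383 to 1662 in controls and 1008 to 1525 in the cKO. In the later test 1116 of 1465 receptor genes had no control count where even cover by independent reads would leave 101.8, which argues against such even cover only, as amplified reads of a few DNA molecules would leave genes empty too. Genomic DNA captured unevenly, loss of Virma, the difference the design names, and transcription from repeats, which was not tested, stay open.

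Genes that rose may owe part of their rise to cumulus cells carried along, since Inha and Gja1 varied between libraries. More cells of an unchanged kind would raise their markers alike, but of 10 tested markers Inha, Nr5a2 and Kitl rose (log2 fold changes 1.40, 1.22 and 0.69) and Cyp19a1, Fshr and Inhbb fell (-1.11, -1.64 and -1.48), with heterogeneity Q = 116, and 54.1 without Kitl and Nr5a2. The planned comparison of cKO replicate 1 with control replicate 4, in which 98.8% of the 2883 risen genes were higher, decides nothing, as the genes were called on these libraries and every one of the 16 pairs of libraries gave 97.3% or more. A lower share of oocyte RNA would lower oocyte markers alike, but the log2 fold changes of Zp3 and Bmp15 differed by 6.06 times their joint standard error, and over the 10 oocyte markers, of which 4 fell, heterogeneity Q was 78.4. These unlike marker changes argue only against a like shift of all markers as the sole cause. More cumulus cells, or a lower share of oocyte RNA, alongside other changes would also give unlike markers and stay open. A change in the kind or state of cumulus cells stays open too, as does loss of Virma, untested.

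The use of alternative last exons may have shifted downstream. Of 211 genes with at least 2 tested last exons and a called one, the farthest downstream gained over the farthest upstream in 140 (66.4%, exact 95% interval 59.5 to 72.7, exact binomial p = 2.34e-06), and of all 405 genes with at least 2 tested last exons in 245 (60.5%). Hhat, Crb1, Lrriq3 and Auh go this way and Ptprd the other way, and genes are not independent replicates, so the p is a description. A difference in coverage along transcripts stays open: the mean log2 ratio of last to internal exon counts differed by 0.0431, but single genes went both ways (SD 0.882 over 1713 genes), so the mean decides nothing. Over the 71 genes with a called last exon that had this ratio, the mean difference was -0.268 (SD 1.17), which decides nothing either. Whether the upstream last exons belong to the same transcripts or to separate short ones cannot be read from exon counts.

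A hypothesis that the direction of change follows the length of the longest coding exon, where m6A often lies, found no relation of size across 7991 coding genes (Spearman rho -0.0258, permutation p = 0.0206 over 5000 permutations, across genes, which are not independent). GC content (rho 0.000776) and countable exon length (rho -0.00151) gave no relation either.

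For the genes changed in level, 1 of 35 splits of the 8 libraries, the real one, gave as many (5856, and 0 in the highest other split). Exon usage gave the same, with 1 of 35 splits (671, and 0 in the highest other). Every other split mixes control and cKO libraries, so the difference between the groups adds to the spread within each side. Few calls in those splits were thus likely in advance. As 1 of 35 is also the smallest share possible, these comparisons do not exclude chance. For the gene lists with camera the real split gave 0 and other splits up to 5; with a real count of 0 all 35 of 35 splits give as many, so the comparison says nothing about chance.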
